A study of Cryphonectria parasitica with 15 samples.

How the data were processed

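The 15 libraries of Cryphonectria parasitica mycelium were grouped by the strain or strains that the labels give for each, with 3 libraries per group. The authors deposited 1 table of read counts, whole numbers per row and library that were not normalized. STAR 2.7 and StringTie 2.1.3 are named in the submitters' processing notes, without their settings, and the genome build and the strand setting of the counting are not given in the sources used here. All 15 columns of the table were matched to samples by their descriptions. The table held 12190 rows, of which 583 have IDs that begin with CPNOV and 142 had no read in any library. Reads of near-identical or overlapping genes may be split or shared by the counting, which could not be examined. The descriptions place 5 libraries in 1 sequencing run (all of EP155 and P74-3 replicates 1 and 2) and 10 in another. They also give the 3 DZ-66+P74-3 libraries sequencing index names of another series than all other libraries. Whether that group was prepared apart is not given, and such a preparation could not be told apart from the group. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of replicates held identical counts or differed as little as sampling noise, since the lowest chi-square per degree of freedom in a pair was 12.24.

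Counts were tested with edgeR 4.0.16 in R 4.3.3. Rows were kept by filterByExpr on the 5 groups, which left 11627 and removed 563, and library sizes were scaled by TMM. A quasi-likelihood model with robust estimation and 1 coefficient per group was fitted to all 15 libraries. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05 and no minimum fold. Standard errors given with edgeR changes are the size of the log2 fold change over the square root of the test's F statistic. They are not direct estimates and may be unreliable where a group has few reads. For genes outside both monocultures, or against all 4 control groups, the largest p of the component tests was used where all changes had 1 sign, and the fold given is the smallest of the components. CPM values are TMM-scaled unless given as a share of counts or used in the estimate of each partner's RNA. For that estimate CPM were scaled by total counts alone. The estimate of each partner's RNA used marker genes chosen in the monocultures alone, at least 32-fold apart with a mean of at least 10 CPM in their own strain. In that estimate the median over markers of the ratio of mixture to monoculture CPM was taken for each partner. Folds against a group with 0 reads were computed against a floor of 3 counts over the group, and ratios over 1 to 3 reads carry exact binomial intervals at 95%. The comparisons between groups, their tests and most alternatives were fixed before the data were examined. Further tests chosen after the data or related results had been seen are named as such below.

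In counts simulated from the rows' means, with 200 changed genes, the comparison of the mixtures recovered 92% of genes changed 2-fold and 100% of those changed 4-fold, of 11562 tested, and called 11 unchanged genes. In these simulations the changed genes were drawn from rows with a mean of at least 5 CPM, so recovery at lower levels was not measured. The test against both monocultures recovered 90% and 100% of 11562 tested, and the test against all 4 control groups 89% and 100%. The comparison of EP155 with P74-3 recovered 92% and 99% of 11570 tested. In 5 simulations of mixtures of unresponsive strains in equal parts, 0 genes were called outside both monocultures in either mixture, and 815 to 882 between the mixtures. The difference of the departures called 14 to 19 genes in them against the mean of log2 levels, and 0 against the arithmetic mean. That arithmetic test recovered 88% of genes changed 2-fold and 100% of those changed 4-fold, of 11562 tested.

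A table for the assembly GCF_011745365.1 of strain EP155 was compared with the row IDs, and the numbers of 11586 IDs equalled the number in a locus tag, 135 of them with a symbol. Mean levels were unrelated to the annotated length of the gene so matched, with a Spearman correlation across genes of -0.0122, within the range of -0.0309 to 0.0361 given by 1000 shuffles. The symbols were therefore not used to name genes, and no coordinate, length or neighbour from that table is reported for any gene. This departs from the rule for named genes fixed beforehand. Of 129 tested rows with a symbol, 27 higher and 21 lower in EP155+P74-3 than in DZ-66+P74-3 would have qualified for naming. The table gave no product text, so the gene lists fixed beforehand by words in the product could not be built. No list by product or symbol was tested for a change between groups, while rows whose IDs begin with CPNOV were compared as a class. A list of 7 vacuolar ATPase subunits, made from the symbols, served only to examine the labels. The names used follow the part of the rule for IDs without names. In each comparison they are the 2 largest rises and 2 largest falls among called genes whose libraries did not overlap between the groups compared and whose higher group had a mean of at least 5 CPM. Chance alone leaves 10% of genes without overlap for 3 libraries against 3.

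The alternatives were median-of-ratios size factors, DESeq2 1.42.0, no filter, a minimum of 2-fold, fits of the compared groups alone, each library left out, the replicate number as a block, the sequencing run as a covariate, other definitions of the mean of the monocultures, and other choices of marker genes. limma 3.58.1 was used for the comparisons with the arithmetic mean of the monocultures, on log2 CPM values computed from the deposited counts.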

Results

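RNA levels were measured by RNA sequencing in mycelium of Cryphonectria parasitica, the filamentous fungus that causes chestnut blight, grown on cellophane over agar. The series addressed which genes take part in allorecognition, the process by which a fungal individual tells its own hyphae from those of another strain. There were 15 libraries in 5 groups of 3. The strains EP155, P74-3 and DZ-66 were each grown alone, and P74-3 was grown in a mixture with EP155 or with DZ-66. The EP155+P74-3 mixture was the experimental group, and the other 4 groups were its controls. Total counts per library ranged from 20228815 to 87509698. They ranged from 41791285 to 52241825 in EP155+P74-3 and from 42716633 to 70335556 in DZ-66+P74-3. Genes are named below by their IDs in the count table, because no gene name could be tied securely to the counts, and no function is given for any of them.

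The EP155+P74-3 mixture stood apart from all 12 control libraries. The first principal component of the log2 CPM values held 50% of the variance and separated the 3 EP155+P74-3 libraries from the rest, while the second, with 20.5%, separated P74-3 from EP155 and DZ-66. The DZ-66+P74-3 libraries lay between those of DZ-66 and P74-3 on the second component. The third component, with 14.4%, split the libraries by sequencing run without overlap. Scores ran from 20.6 to 33.8 in the run that holds EP155 and from -39.9 to 9.8 in the other. P74-3 replicates 1 and 2 scored 20.9 and 20.6, and replicate 4, from the other run, scored 4.5. Only P74-3 was in both runs, so strain and run are not told apart on this component. The most abundant gene, 320076, took 6.29% of counts in EP155, 7.36% in P74-3, 9.17% in DZ-66 and 8.28% in DZ-66+P74-3, but 2.29% in EP155+P74-3. Its level was 21246 ± 3462 CPM in EP155+P74-3 and 84218 ± 4486 CPM in DZ-66+P74-3 (SD, n = 3 each), a log2 fold change of -1.99 with a standard error of 0.12 and an adjusted p of 7.68e-09 by edgeR's quasi-likelihood test.

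**Figure D1:**
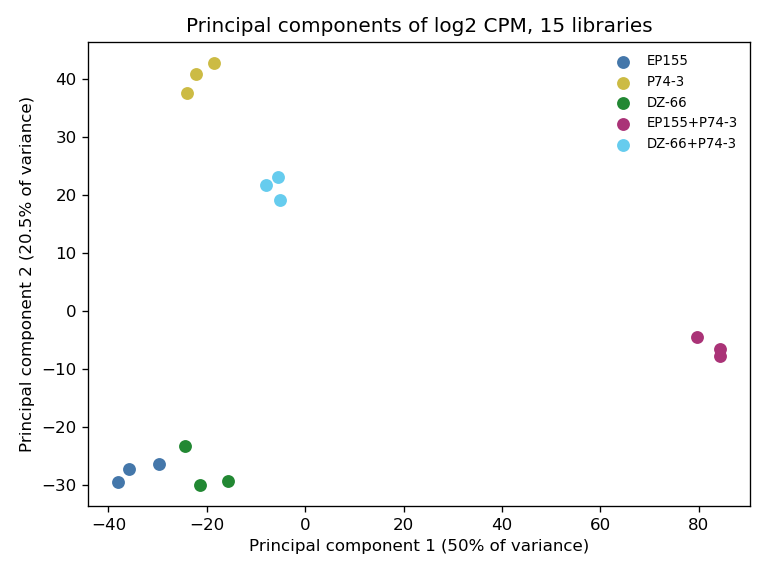
Each point is 1 library, placed by its scores on the first (x axis) and second (y axis) principal component of log2 CPM, with the percentage of variance on each axis, and coloured by group. The 3 EP155+P74-3 libraries lie to the right of all 12 control libraries.

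The comparison of the mixtures asked what differed when P74-3 met EP155 rather than DZ-66. A total of 2398 genes were higher and 2687 lower in EP155+P74-3 than in DZ-66+P74-3, of 11627 tested. Large changes were mostly rises, with 188 genes at least 8-fold higher against 31 at least 8-fold lower, and 39 at least 64-fold higher against 0 lower. Gene 102797 rose from 3.46 ± 1.18 to 14904 ± 997 CPM (SD, n = 3 each), a log2 fold change of 12.05 with a standard error of 1.3. CPNOV.8539 had 0 reads in DZ-66+P74-3 and 865 in EP155+P74-3, and was at least 283-fold higher against a floor of 3 counts over the group. Gene 234231 fell from 705 ± 226 to 33.7 ± 18.9 CPM (SD, n = 3 each), a log2 fold change of -4.39 with a standard error of 0.5. Gene 354712 fell from 48.6 ± 13.4 to 2.65 ± 1.38 CPM (SD, n = 3 each), a log2 fold change of -4.22 with a standard error of 0.56. Among genes abundant on average over all libraries, more fell than rose. Of the 90 genes with a mean of 1000 CPM or more over all libraries, 46 were lower and 12 higher in EP155+P74-3. Of the 796 genes with a mean under 1 CPM, 188 were higher and 107 lower. Most libraries in that mean are controls. The bins themselves therefore favour falls among abundant genes and rises among scarce ones, and how much of the contrast this explains was not tested. Calls were made with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, and both mixtures came from 1 sequencing run. The DZ-66+P74-3 libraries carry index names of another series, so a separate preparation of that mixture cannot be told apart from its strains. The adjusted p of the 4 named genes ranged from 2.87e-08 to 7.53e-05. With a 2-fold minimum, 736 genes were higher and 707 lower.

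**Figure D2:**
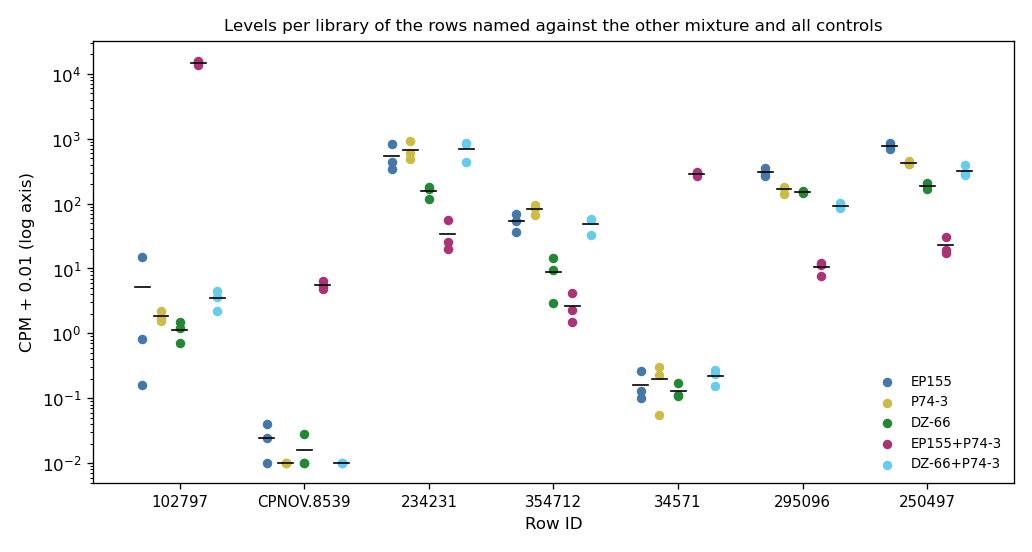
CPM plus 0.01 on a log axis for the genes named in the comparisons of EP155+P74-3 with DZ-66+P74-3 and with all 4 control groups, identified on the x axis by row ID. Points are libraries, coloured by group, and black lines are group means. Gene 102797 averaged 14904 CPM in EP155+P74-3, and its level in 1 EP155 library lay above those of the other control libraries.

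A mixture of strains that do not respond to each other would lie between its monocultures whatever their proportion, so genes outside both monocultures were counted. In EP155+P74-3, 2217 genes were higher and 2176 lower than in both EP155 and P74-3, and 763 and 508 with a 2-fold minimum. Gene 102797 was at 5.25 ± 8.28 CPM in EP155 and 1.83 ± 0.361 CPM in P74-3 (SD, n = 3 each). Gene 34571 rose from 0.152 ± 0.0855 CPM in EP155 and 0.185 ± 0.125 CPM in P74-3 to 288 ± 20.2 CPM in the mixture (SD, n = 3 each), 1600-fold by the smaller of the 2 fitted fold changes. Gene 330510 fell to 1.24 ± 0.585 CPM from 26.4 ± 7.85 CPM in EP155 and 32.5 ± 7.4 CPM in P74-3 (SD, n = 3 each). Gene 354712 fell to 2.65 ± 1.38 CPM from 53.2 ± 16.9 and 82.4 ± 14.5 CPM in the same order (SD, n = 3 each). Each call needed edgeR's quasi-likelihood test against both monocultures, with the larger p adjusted, and the named genes had adjusted p from 5.98e-13 to 0.000383. EP155 was sequenced in another run. Against P74-3 alone 6371 genes differed with all 3 of its libraries and 4570 with the 1 library of the mixture's own run, which was assumed to vary like the other groups. With the run as a covariate 2430 genes lay outside both monocultures.

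In DZ-66+P74-3, 93 genes were higher and 128 lower than in both DZ-66 and P74-3, while with a 2-fold minimum 20 were higher and 3 lower. Gene 327156 rose to 5.94 ± 1.96 CPM from 0.81 ± 0.272 CPM in DZ-66 and 1.32 ± 0.676 CPM in P74-3 (SD, n = 3 each). Gene 71397 rose to 20.7 ± 4.51 CPM from 3.61 ± 0.226 and 4.72 ± 0.921 CPM in the same order (SD, n = 3 each). Gene 107767 fell to 50.4 ± 5.39 CPM from 250 ± 37.1 CPM in DZ-66 (SD, n = 3 each), and its 3 P74-3 libraries were at 130.3, 136.3 and 225.5 CPM. Gene 325579 fell to 233 ± 17.9 CPM from 554 ± 14.1 CPM in DZ-66 and 597 ± 138 CPM in P74-3 (SD, n = 3 each). The 4 had adjusted p from 0.00147 to 0.00742 by edgeR's quasi-likelihood test. With P74-3 represented by its only library of the same run, assumed to vary like the other groups, 2 genes were called, and 1 with the run as a covariate. Under the covariate the 221 genes kept their direction against P74-3, where the median size of the log2 fold change went from 0.65 to 0.56 and the median standard error from 0.1 to 0.13. The named genes lost their calls there, at adjusted p from 0.0687 to 0.116 by edgeR, and their log2 fold changes against P74-3 went from 2.16 ± 0.32 to 1.5 ± 0.35 for gene 327156, from 2.15 ± 0.23 to 1.92 ± 0.35 for gene 71397, from -1.7 ± 0.24 to -1.37 ± 0.3 for gene 107767 and from -1.36 ± 0.14 to -1.05 ± 0.16 for gene 325579 (± standard error). Between the 1 P74-3 library of that run and the 2 of the other edgeR called 3 genes, and 948 were at an unadjusted p under 0.05, with the spread of the single library taken from the other groups, so this count does not bound the effect of the run. Leaving out single libraries gave 146 genes without P74-3 replicate 1, 140 without P74-3 replicate 2, 97 without DZ-66 replicate 2, 409 without DZ-66 replicate 3, 140 without DZ-66+P74-3 replicate 1, 68 without DZ-66+P74-3 replicate 3 and 25 without DZ-66+P74-3 replicate 4.

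The departure of each mixture from the mean of the log2 levels of its monocultures was compared between the mixtures, with equal parts assumed. The departure of 2315 genes was higher and that of 2387 lower in EP155+P74-3 than in DZ-66+P74-3, and of 832 and 619 with a 2-fold minimum. Gene 102797 differed by 10.91 on the log2 scale with a standard error of 1.3. Gene 354712 differed by -5.5 with a standard error of 0.62, and gene 234231 by -5.29 with a standard error of 0.55. CPNOV.8539 met the rule too, but its fitted difference rests on groups with 0 to 2 reads, and its call by edgeR's quasi-likelihood test ended without DZ-66 replicate 2 and with the sequencing run as a covariate, at an adjusted p of 1 in both. The 4 had adjusted p from 1.03e-05 to 0.0015 by the same edgeR test. Equal parts of RNA give the arithmetic mean of 2 levels, not the mean of their log2 values. Against arithmetic means, tested with limma on log2 CPM in place of edgeR, 4653 genes were called in equal parts and 4579 in the parts estimated from marker genes, and the difference for gene 354712 was -4.86 and -4.43, for gene 234231 -4.99 and -4.66, and for gene 102797 12.06 and 12.2 in the same order. With the sequencing run as a covariate edgeR called 3900 genes.

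Against all 4 control groups at once, 1221 genes were higher and 1239 lower in EP155+P74-3, and 516 and 286 with a 2-fold minimum. The genes that were higher made up 14.6% ± 0.65 of all counts in EP155+P74-3 (SD, n = 3), and between 4.26% and 4.53% on average in the control groups. Those that were lower made up 11.4% ± 0.752 of counts (SD, n = 3) there, against 24.9% to 26.5%. These shares describe genes chosen by the same comparison. In 25 genes every control library was under 1 CPM and every EP155+P74-3 library at 10 CPM or more, and 0 genes showed the opposite. Gene 34571, at 288 CPM the most abundant of the 25, was at 0.122 ± 0.0362 CPM in DZ-66 and 0.21 ± 0.0606 CPM in DZ-66+P74-3 (SD, n = 3 each). Gene 295096 was at 10.4 ± 2.45 CPM in EP155+P74-3 and at 92.2 ± 8.17 CPM in DZ-66+P74-3, the lowest control group (SD, n = 3 each). Gene 250497 was at 22.7 ± 7.13 CPM against 186 ± 19.5 CPM in DZ-66, the lowest control group (SD, n = 3 each). Calls needed edgeR's quasi-likelihood test against each control group, and the named genes had adjusted p from 6.65e-13 to 2.9e-05. With the run as a covariate edgeR called 1796 genes. A fit to the control libraries of the same run left EP155 out and P74-3 with 1 library, so its count is not given.

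**Figure D3:**
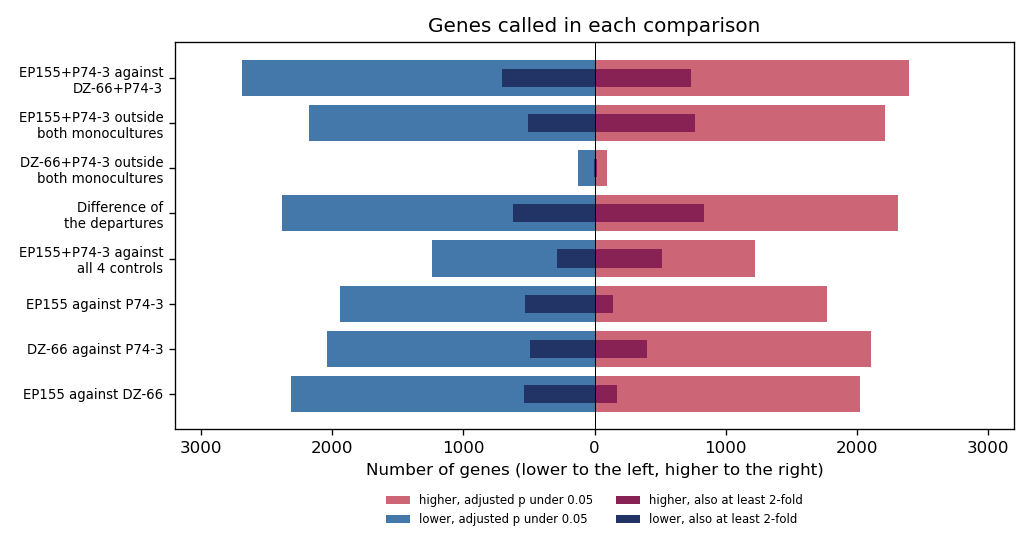
Horizontal bars give the number of genes called at an adjusted p under 0.05 in each comparison, lower to the left and higher to the right, with the part that also changed at least 2-fold in the darker inner bars. EP155+P74-3 had 4393 genes outside both of its monocultures, and DZ-66+P74-3 had 221.

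The strains themselves differed when grown alone. Between EP155 and P74-3, 1776 genes were higher in EP155 and 1945 lower, and with a 2-fold minimum 143 were higher and 529 lower. Gene 281316 had 15802 reads in EP155 and 3 in P74-3, a ratio of 5500 with a 95% exact interval of 1880 to 26700. CPNOV.7930 had 2593 reads in EP155 and 1 in P74-3, a ratio of 2710 with an interval of 486 to 107000. CPNOV.3005 had 1 read in EP155 and 14568 in P74-3, and CPNOV.2070 was at 0.0501 ± 0.00823 CPM in EP155 and 132 ± 13.5 CPM in P74-3 (SD, n = 3 each). These intervals cover counting error only. Within the run that holds EP155, with 2 P74-3 libraries, edgeR's quasi-likelihood test called 2395 genes. With all libraries the named genes had adjusted p from 2.48e-15 to 1.68e-11 by that test of edgeR. The count of 2395 is also the value without P74-3 replicate 4, and 2372 genes were called without EP155 replicate 2.

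Between DZ-66 and P74-3, 2108 genes were higher in DZ-66 and 2042 lower, and with a 2-fold minimum 403 were higher and 489 lower. Gene 281316 had 14954 reads in DZ-66 against 3 in P74-3, a ratio of 4580 with a 95% exact interval of 1570 to 22200. CPNOV.7930 had 3491 reads against 1, a ratio of 3210 with an interval of 576 to 127000. Gene 67610 had 0 reads in DZ-66 and 4529 in P74-3, at least 1640-fold lower in DZ-66, and CPNOV.3005 had 0 reads in DZ-66 and was at least 5280-fold lower. Against the 1 P74-3 library of the same run, edgeR's quasi-likelihood test called 2093 genes, where that library was assumed to vary like the other groups. With all libraries the named genes had adjusted p from 5.27e-13 to 9.27e-12 by edgeR.

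Between EP155 and DZ-66, 2026 genes were higher in EP155 and 2315 lower, and with a 2-fold minimum 168 were higher and 539 lower. Gene 67610 was at 30.1 ± 4.83 CPM in EP155 (SD, n = 3) and at least 1660-fold lower in DZ-66. Gene 323413 was at 234 ± 1.73 CPM in EP155 and 2.04 ± 0.32 CPM in DZ-66 (SD, n = 3 each). Gene 329622 was at 0.872 ± 0.235 CPM in EP155 and 89.7 ± 24.8 CPM in DZ-66, and gene 69121 at 1.09 ± 0.111 and 96.8 ± 12.2 CPM (SD, n = 3 each). These strains share no sequencing run, so the strain and the run are tied together only through P74-3. The named genes had adjusted p from 7.73e-13 to 2.26e-10 by edgeR without a term for the run. With the run as a covariate edgeR's quasi-likelihood test called 392 genes.

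The RNA of each partner in the mixtures was estimated from genes at least 32-fold apart between the monocultures. In DZ-66+P74-3 the DZ-66 share was 29.8% ± 2.47 (SD, n = 3), from 9 DZ-66 and 6 P74-3 marker genes. In EP155+P74-3 the EP155 share was 51.9% ± 2.48 (SD, n = 3), from 3 EP155 and 5 P74-3 marker genes. The ratios of the markers to their levels in monoculture, which add to about 1 when marker genes do not respond, were 0.289 and 0.68 in DZ-66+P74-3 with a sum of 0.97 ± 0.0166, and 0.387 and 0.359 in EP155+P74-3 with a sum of 0.746 ± 0.0108 (SD, n = 3 each). With other marker choices the sum in EP155+P74-3 was 1.03 ± 0.0747 for markers 8-fold apart, 0.578 ± 0.0229 for a minimum of 50 CPM and 0.558 ± 0.0102 for summed CPM (SD, n = 3 each). The EP155 estimate moved with the markers, to 59.6% with markers 8-fold apart, 37.3% with a minimum of 50 CPM and 35.5% from summed CPM, so which partner gave more RNA was not settled for this mixture.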

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

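The tests of the proportion of the partners, of thinned mixtures and of arithmetic means were chosen after related results had been seen, and those of all libraries thinned and of the 20 most abundant genes after the data had been seen, with bounds set before their own results. The departures of the mixtures from the mean of their monocultures differed, by a test of the difference itself, in 4702 genes. Among the named genes the difference on the log2 scale was 10.91 for gene 102797, -5.5 for gene 354712 and -5.29 for gene 234231. Against arithmetic means of the monocultures in the estimated parts these were 12.2, -4.43 and -4.66. The 10.67 of CPNOV.8539 is a fitted value over groups with 0 to 2 reads and is no bound, and its adjusted p by edgeR was 1 with the run as a covariate and without DZ-66 replicate 2. Its level in EP155+P74-3 was at least 283-fold that in DZ-66+P74-3. In 1 of 100 drawn splits of the 12 libraries, the real one, there were as many calls, and the highest of the others gave 3143. That split kept the 3 EP155+P74-3 libraries together. The splits dealt libraries of EP155, DZ-66 and both mixtures anew over the groups, which also differ by strain. They therefore argue only against all 12 libraries being alike and do not decide chance for the difference itself.

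For the genes called between the mixtures, without the 20 most abundant genes, 96.5% of the others were still called in the same direction. This argues against a few genes taking most of the counts as the cause of the calls. Without those 20 genes 2589 were higher and 2499 lower, against 2398 and 2687 with them. Which direction held more calls therefore depended on those genes. Of the called genes 59% were also called outside both monocultures of EP155+P74-3 in the same direction. If the run had no effect, this argues against the proportion of the partners as the whole cause. EP155 was in another run. With the run as a covariate the genes outside both monocultures fell from 4393 to 2430, and their overlap was not counted. Independent lists would share 18.9%. Simulated mixtures of unresponsive strains had 0 genes outside both monocultures and no run effect, so they could share none. Part of the excess over independent lists may come from the EP155+P74-3 libraries that both comparisons use. Thinning the mixtures to 41791285 counts, their lowest total, left at least 97% still called in 10 draws. Thinning every library to 20228815 counts left 88.5%. That is below the 90% set before that test, which alone did not decide, but far above the under 50% that library size as the cause predicted. Together these values argue against library size as the whole cause. A response of P74-3 and EP155 to each other, which the design names, stays open as a hypothesis for the 3000 genes also outside both monocultures. For the others both a response and the strains' own differences stay open. Of the genes called between the mixtures, 3924 also differed in the same direction in the departure from the mean of the monocultures. That count assumed equal parts and had no term for the run.

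For the comparison of the mixtures, which gave 5085 genes, the highest of the other splits of the 6 libraries gave 0. The same held for EP155 against P74-3 with 3721 genes, DZ-66 against P74-3 with 4150 and EP155 against DZ-66 with 4341. In each of these only 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. For EP155+P74-3 outside both monocultures 1 of 100 splits gave as many as 4393. The highest other gave 4260, with the mixture's libraries intact and those of EP155 and P74-3 exchanged. For EP155+P74-3 against all 4 control groups 1 of 100 splits gave as many as 2460, and the highest other gave 0. The splits of these comparisons argue against all the compared libraries being alike, which is less than excluding chance for either result. For DZ-66+P74-3 outside both monocultures 4 of 100 splits gave as many as 221, a share under 0.05, yet the highest other gave 1330. The splits above the real one set the 3 P74-3 libraries against those of DZ-66 and DZ-66+P74-3 dealt over 2 groups, which points to the difference of P74-3 from both. The splits also ignored the sequencing run, and with the run as a covariate 1 gene was called. They therefore do not decide chance for this mixture.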

How the results depend on the processing

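Tests within 1 run for EP155, for EP155+P74-3 and for all controls, fits without the 20 most abundant genes or with thinned counts, arithmetic means for the difference of the departures, and the left-out libraries for the partner shares were chosen after seeing the data. Median-of-ratios size factors and no filter kept every count of calls within 1.5 times. A minimum of 2-fold left 1443 genes between the mixtures, 1271 and 23 outside the monocultures of EP155+P74-3 and DZ-66+P74-3, 1451 for the difference of the departures, 802 against all 4 controls, 672 for EP155 against P74-3, 892 for DZ-66 against P74-3 and 707 for EP155 against DZ-66. That follows from its construction. With the run as a covariate the counts were 2430 and 1 outside the monocultures in the same order, 2395 for EP155 against P74-3, 2077 for DZ-66 against P74-3 and 392 for EP155 against DZ-66. With P74-3 by its library of the same run they were 2 for DZ-66+P74-3 outside its monocultures and 2093 for DZ-66 against P74-3, and for EP155 against P74-3 within 1 run 2395. Fits of the compared groups alone, which hold fewer samples, gave 49 for DZ-66+P74-3 outside its monocultures, 2083 for DZ-66 against P74-3 and 2649 for EP155 against DZ-66. DESeq2 gave 453 for DZ-66+P74-3 outside its monocultures, and the cause was not tested. Against the mean of the log2 levels of the monocultures, which asks for less than lying outside both, 6842 and 2250 genes differed in EP155+P74-3 and DZ-66+P74-3, and against the arithmetic mean 6800 in EP155+P74-3. The difference of the departures gave 4497 to 4760 genes against arithmetic means in equal parts or with the estimates of the EP155 share. The EP155 share was 59.6%, 37.3% and 35.5% with markers 8-fold apart, a minimum of 50 CPM and summed CPM, and the DZ-66 share 32.8% with summed CPM, and the cause was not tested.

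Leaving out 1 library at a time gave 4252 to 5461 genes between the mixtures, 3704 to 4698 for EP155+P74-3 outside its monocultures, 25 to 409 for DZ-66+P74-3 outside its monocultures, 3898 to 5199 for the difference of the departures, 2021 to 2628 against all 4 controls, 2372 to 4115 for EP155 against P74-3, 3376 to 4661 for DZ-66 against P74-3 and 3077 to 4567 for EP155 against DZ-66. The EP155 share ranged from 50.6% to 53.5% and the DZ-66 share from 28.4% to 31.5%. Libraries with the same replicate number did not consistently deviate together, with correlations from -0.196 to 0.298 over 21 pairs against -0.318 to 0.292 over 69 other pairs, so the numbers are not taken as pairing. With the replicate block DZ-66+P74-3 had 83 genes outside its monocultures, and no other count moved by over 1.5 times. For the 32 uses of named genes 741 alternative values kept direction and call, 10 kept the direction and lost the call and 0 reversed. These genes were chosen as the largest called changes, and some alternatives left out libraries of groups not compared. The tally therefore says little of the other calls. Gene lists were not run under any alternative.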

Other observations

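The tests of carry-over, of row labels, of neighbouring rows, of CPNOV rows within bins of level and of their share without 1 row were chosen after seeing the data. Rows whose IDs begin with CPNOV held 2.45% ± 0.0641 of counts in EP155+P74-3, 1.61% ± 0.00649 in DZ-66+P74-3, 2.02% ± 0.0219 in EP155, 1.73% ± 0.104 in P74-3 and 1.74% ± 0.0532 in DZ-66 (SD, n = 3 each). The exact two-sided permutation p between the mixtures was 0.1, the smallest that 3 libraries against 3 allow. A single row, CPNOV.6992, singled out after its values were seen, held 0.734% ± 0.0415 of counts in EP155+P74-3 and 0.000649% ± 5.69e-05 in DZ-66+P74-3 (SD, n = 3 each). Without it the class held 1.71% ± 0.0244 in EP155+P74-3 (SD, n = 3), within the range of the control groups, 1.61% to 2.02%. CPNOV rows had a lower median level, 1.86 against 4.97 log2 CPM, and calls vary with level, so the 556 tested CPNOV rows were compared with the other 11071 within 10 bins of level by an exact conditional test, adjusted over 16 tests in which genes are counted as independent. In DZ-66, 25.4% of CPNOV rows were lower than in P74-3, against 18.9% of the others at the same levels (adjusted p = 0.00188), and 11.9% were higher, against 15.2% (adjusted p = 0.0481). In EP155, 13.8% were higher than in P74-3, against 9.6% (adjusted p = 0.0035), while 23.4% were lower, against 20.8% (adjusted p = 0.153). Without the bins Fisher's exact test gave the reverse for EP155, with an adjusted p of 0.417 for higher and 0.000248 for lower. CPNOV rows lower in EP155 than in DZ-66 made up 15.1%, against 21.3% (adjusted p = 0.0019). All these calls come from fits without a term for the sequencing run. With that term the calls between EP155 and DZ-66, strains that share no run, fell from 4341 to 392. Those between EP155 and P74-3 fell from 3721 to 2395 and those between DZ-66 and P74-3 from 4150 to 2077. The term rests on the P74-3 libraries alone, so these falls mix lost precision with any effect of the run. Between the mixtures, which share a run, 18.3% of CPNOV rows were higher in EP155+P74-3, against 25.1% (adjusted p = 0.00199), and 25.9% lower, against 21.4% (adjusted p = 0.0267). Without the bins Fisher's exact test gave an adjusted p of 0.288 for higher and 0.22 for lower, so these differences appear only within the bins. In EP155+P74-3, 13.5% were higher than both monocultures, against 22.5% (adjusted p = 1.17e-05), and 20% lower than both, against 15.2% (adjusted p = 0.0098), also without a term for the run. Fisher's exact test without the bins gave an adjusted p of 0.0019 for higher and 0.465 for lower there. Of the genes called between the mixtures, 1183 were also called between EP155 and DZ-66 in the same direction and 1035 in the opposite direction, with the same limit for that pair of strains.

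Of the 221 genes outside both monocultures in DZ-66+P74-3, 153 were also outside both in EP155+P74-3 in the same direction and 9 in the opposite direction. Independent lists would share 17.7 higher and 24 lower genes, where 62 and 91 were shared. In 5 simulations of mixtures of unresponsive strains 0 genes lay outside both monocultures, so they could share none and give no measure of the overlap that shared libraries bring. Both comparisons use the 3 P74-3 libraries, which cannot be divided into parts of at least 2, so part of the excess may come from these shared controls, and with the sequencing run as covariate only 1 gene was called outside both monocultures in DZ-66+P74-3.

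Genes induced in EP155+P74-3 were seen at low levels in control libraries. For 10 genes at 100 CPM or more there and over 100-fold above every control group, the median ratio of CPM in the P74-3 library of the same run to those of the other run was 0.906. Carry-over between libraries of 1 run would raise that ratio, but the test rests on 1 library and does not decide. Gene 102797 and CPNOV.6992 reached 1.52 and 6.17 CPM in the P74-3 library of the same run and 1.98 and 4.23 CPM in the other run.

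A candidate explanation for the missing relation between level and annotated length, at -0.0122 across genes, is that the row labels no longer match the counts. Genes are not independent replicates. The 167 matched genes of at most 200 bp had a median of 5.14 log2 CPM and the longer ones 4.96. Shifting the labels by up to 12 rows either way gave correlations from -0.0122 to 0.021. The spread of 7 vacuolar ATPase subunits was 1.93 on the log2 scale, and 23% of random lists were as tight or tighter, which decides nothing. A library protocol that reads transcript ends would also weaken a relation with length, and it was not tested.

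Neighbouring rows of the table changed together between the mixtures. The Spearman correlation of the log2 fold change of adjacent rows was 0.081 over 11071 rows, above the highest of 1000 shuffled orders at 0.0274 (permutation p = 0.001, the smallest they can give). Among genes higher than in all 4 control groups there were 11 runs of at least 4 adjacent rows, and at most 6 in shuffled orders. Among genes lower than in all 4 there were 9 such runs, and at most 8 in shuffled orders. The longest run was no longer than in shuffled orders, with 6 rows against up to 7 for higher genes and 6 against up to 6 for lower genes. The rows may follow an order in which co-regulated genes are neighbours. The same correlation for neighbours in the reference that are not adjacent in the table was 0.0112, against 0.0673 for those that are.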
